A study of Escherichia coli K-12 with 16 samples.

How the data were processed

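RNA was measured in 16 libraries of Escherichia coli K-12, 2 for each combination of genotype (wild type or rnr deletion), oxygen supply (oxic, or anoxic with nitrate) and carbon source (glycerol, or glycerol plus propionate). Per the labels' protocols, cells grew at 37 °C in M4 minimal medium with casein hydrolysate, 50 mM glycerol and, where given, 10 mM propionate and 50 mM potassium nitrate. RNA was isolated with the RNeasy Protect kit, treated with DNase, depleted of ribosomal RNA with MICROBExpress and made into strand-specific TruSeq libraries, which were sequenced as 2 reads of 50 nt per fragment. The deposited values are counts, whole numbers of reads per gene and library, without normalization. Per the submitters' processing notes CASAVA 1.8.1, Bowtie2 and HTSeq were used; the versions of the latter 2, the settings, the genome build and the use of strand in counting are not given in the sources used here, so genes with near-identical copies or overlapping neighbours carry an added uncertainty.

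Each library lists 4321 genes by locus tag, of which 4314 matched a gene of the RefSeq table of assembly ASM584v2, used only for names and neighbour order, and 7 did not. They comprise 4178 protein-coding genes and 136 pseudogenes, with 0 rRNA or tRNA genes, and 5 summary entries that name no gene were left out of all gene values. Reads assigned to genes numbered 863240 to 1774647 per library, which is 3.48 to 7.08% of all records, while 83.2 to 86.4% were set aside as of too low alignment quality and 7.95 to 9.07% were assigned to no listed gene. Reads of no listed gene were 1.95 to 2.36 times the gene counts in the wild type and 1.28 to 1.88 times in the mutant. They can lie outside genes, on RNA genes that are not listed or, as the use of strand is not given, on the opposite strand of listed genes. A gene at 0 counts in a library could hold up to 3 counts at 95% confidence, a floor of 1.69 to 3.48 CPM, and 207 to 323 genes stood at 0 per library. Intervals and floors from counts cover counting error only. Between the 2 libraries of a group the chi-square per degree of freedom was 2.99 to 16.7 in 7 groups and 60.2 in wild type anoxic propionate, where 1 is pure counting error, over genes with at least 20 counts.

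Groups were taken from the labels. The submitters' names for the count tables of the mutant carry a term other than rnr, so the assignment of these 8 libraries to an rnr deletion rests on the labels and on the counts of rnr (183 in the mutant against 6988 in the wild type). Counts were analysed in edgeR 4.0.16 under R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total 15, 3531 genes), library sizes were scaled by TMM, and a quasi-likelihood model with robust estimation and 1 mean per group was fitted to all 16 libraries, since 2 libraries per group give little information on spread alone. The common dispersion was 0.0369 and the median prior degrees of freedom 5.03. From this fit 17 contrasts were tested: propionate against glycerol in 4 settings, anoxic against oxic in 4, mutant against wild type in 4 and as their mean, and 4 interactions. Within each contrast p-values were adjusted by Benjamini-Hochberg over all 3531 genes at a threshold of 0.05, and all p-values from edgeR in the text are adjusted in this way. The SE of a log2 change is its size divided by the square root of its F statistic. CPM use TMM-scaled library sizes, log2 CPM for components and for correlations of changes have a prior count of 2, and the tests of technical shares are exact permutation tests. Correlations between the 2 libraries of a group, and the shares of genes over 2-fold apart, instead use log2 of CPM plus 1. They cover genes with at least 20 counts in the pair, scaled to the totals of these genes without TMM.

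The groups, contrasts, tests, alternative settings, 39 gene lists of pathways and regulons (555 gene names, all matched) and the rule for naming genes were chosen before the data were examined. The lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry; 38 lists had at least 3 members tested, and list p-values were adjusted within each contrast over the lists. By the naming rule, each main contrast yields the 12 largest rises and 12 largest falls by log2 change among genes past the threshold whose libraries do not overlap and whose higher group reaches 10 CPM (5 and 5 for mutant-only contrasts and interactions, where for interactions overlap is not checked), up to 4 members of each list described, and rnr, rng, the prp genes and the genes known to be deleted in strain BW25113. Each named rise or fall of a 2-group contrast under the rank part of the rule is therefore seen in both libraries of its group. A change against a group at 0 counts is given as a bound against 3 counts over the group, and one against 1 to 3 counts as a ratio with its counting interval.

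The model was tested on simulated data made from the real counts. In each of 12 contrasts changes were added to 200 genes, all with a mean above 10 CPM over the libraries. At the threshold the model recovered 38 to 53% of 2-fold and 84 to 93% of 4-fold changes in these genes, with 2.24 to 9.4% false among the calls, and camera gave 0 of 100 random lists at p under 0.05 in each of 2 contrasts. Simulated genes were drawn independently of each other, each with the same dispersion in all groups. The simulation therefore cannot show how camera behaves for lists of genes that vary together. Nor can it give the share of false calls where a group varies more than the others, as wild type anoxic propionate does. Alternatives were other size factors (RLE), no filter on low counts, DESeq2 1.42.0 on all libraries, the replicate number as a block, the compared groups alone, each library left out in turn and, for gene lists, the other list tests. Added after the data were seen were a fit without both wild type anoxic propionate libraries and one without flagella genes and genes at or near 0 in 1 genotype. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.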

Results

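The series holds 16 RNA-seq libraries of Escherichia coli K-12, 8 from the wild type and 8 from a strain deleted for rnr. This gene encodes ribonuclease R, an exoribonuclease that degrades structured RNA. Cultures grew at 37 °C in minimal medium on 50 mM glycerol, with or without 10 mM propionate. They had either oxygen or 50 mM nitrate in its place, which gave 8 groups of 2 libraries. All anoxic cultures and no oxic culture had nitrate, so each contrast of anoxic with oxic cells measures the absence of oxygen and the presence of nitrate together, and the 2 cannot be separated. Levels are given in CPM (counts scaled to library size) as mean ± SD, log2 changes with their standard error, and n = 2 libraries per group unless stated. The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

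The transcript of rnr itself was measured first. In the 8 wild type libraries rnr stood at 794.5 ± 396 CPM (374 to 1639 CPM, 6988 counts). In the 8 mutant libraries it stood at 17.2 ± 4.66 CPM (12.7 to 26.3 CPM, 183 counts), which is 2.16% of the wild type mean. In the wild type groups rnr had 776 ± 27.1 CPM in anoxic glycerol, 889.8 ± 139 in oxic glycerol, 1095 ± 769.8 in anoxic propionate and 418 ± 61.2 in oxic propionate. In the mutant groups, in the same order, it had 23.5 ± 3.92, 13.9 ± 0.982, 17.6 ± 2.43 and 13.6 ± 1.21 CPM. The gene after rnr in assembly ASM584v2 is rlmB, which encodes a methyltransferase of ribosomal RNA. Its transcript stood at 102 ± 25.8 CPM in the wild type and 361 ± 64.0 in the mutant (n = 8 each).

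Separately from rnr, several genes had few or no counts in the libraries of 1 genotype. Over its 8 libraries the mutant had 0 counts of araA and araB, of arabinose breakdown, against 91 and 47 in the wild type. It had 0 of rhaB, of rhamnose breakdown, against 9, and 15 of lacZ, the beta-galactosidase gene, against 86. Conversely the prophage genes intZ and yffS had 0 counts in the 8 wild type libraries. In mutant anoxic glycerol intZ had 463 counts, and in mutant oxic propionate yffS had 313. The share of reads that the aligner did not place also split all 16 libraries by genotype. It was 2.40 ± 0.183% in the wild type and 0.667 ± 0.0366% in the mutant (exact permutation p = 1.55e-04, n = 8 each, 12870 splits). Genotype and this share therefore move together in every comparison of mutant and wild type. The absent genes go with genotype over all libraries, but rhaB and lacZ had too few counts to show it in each condition. In anoxic glycerol rhaB had 0 counts in both genotypes, and in anoxic propionate lacZ had 4 in the mutant against 5 in the wild type.

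Genotype and oxygen separated the libraries along the first 2 components, with 44.8% and 32.9% of the variance of log2 CPM. The library pairs of 7 groups correlated across genes at r = 0.969 to 0.986. The pair of wild type anoxic propionate libraries stood apart at r = 0.914, with 18.9% of genes over 2-fold apart against 1.41 to 6.69% in the other groups.

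**Figure D1:**
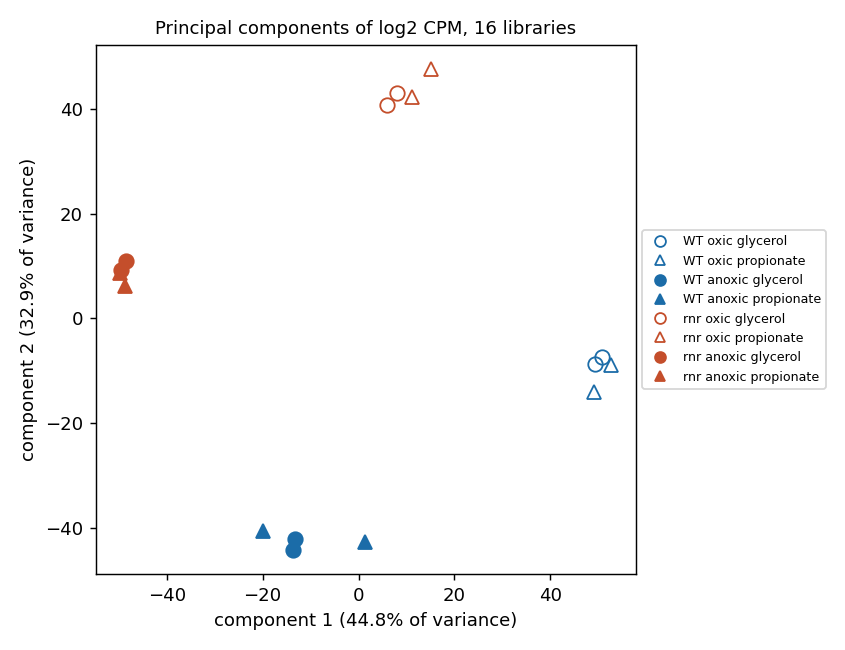
First and second principal components of log2 CPM of the 16 libraries, with the percent of variance on each axis. Wild type is blue and mutant red, oxic open and anoxic filled, glycerol a circle and propionate a triangle; the 2 filled blue triangles, wild type anoxic propionate, lie far from each other.

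In wild type cells without oxygen, genes of nitrate reductase A were higher with propionate and genes of iron-sulphur cluster assembly were lower by the preset list test. Neither list passed with an estimated correlation (adjusted p = 0.678 and 0.5). The genes narH and narJ, of nitrate reductase A, rose, narH to 646 ± 35.1 against 112 ± 51.2 CPM (log2 change 2.53 ± 0.43, adjusted p = 0.0117) and narJ by a log2 change 2.25 ± 0.34, adjusted p = 0.00742. The envelope stress sigma factor gene rpoE rose as well (log2 change 2.05 ± 0.21, 981 ± 247 against 236 ± 20.9 CPM, adjusted p = 3.86e-04). Tyrosine transporter gene tyrP fell (log2 change -3.17 ± 0.27, 43.6 ± 17.1 against 386 ± 48.6 CPM, adjusted p = 8.96e-05), and so did pyrE, of pyrimidine synthesis (log2 change -2.46 ± 0.38, adjusted p = 0.00742). The prp genes of the methylcitrate cycle, the route of propionate oxidation, did not pass. Of these, prpB stood at 290 ± 286 against 95.2 ± 11.4 CPM (adjusted p = 0.256), with 87.6 CPM in replicate 1 and 492 CPM in replicate 2. In replicate 1 narH and narJ were above the glycerol mean (log2 differences 2.64 and 2.59) while prpB was not (-0.11). Whether propionate raised narH and narJ is therefore not settled. The propionyl-CoA synthetase gene prpE stood at 33.8 ± 24.5 against 20.8 ± 10.9 CPM (adjusted p = 0.518). In all, 93 of 3531 tested genes changed, 49 higher and 44 lower. The count of 93 became 15 and 18 without wild type anoxic glycerol replicates 1 and 2, and 270 and 397 without wild type anoxic propionate replicates 1 and 2. Fitted to the compared groups alone, edgeR called 0 genes, with 257 at an unadjusted p under 0.05, while DESeq2 on all libraries called 141. Every call of a single gene given for this comparison ended in that fit to the compared groups, and 0 of 39 named calls were kept in all settings. Leaving out 1 library also ended those of narH (adjusted p = 0.1 without wild type anoxic glycerol replicate 1) and narJ (adjusted p = 0.0669 without wild type anoxic glycerol replicate 1).

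Among the gene lists in this comparison, 3 of 10 genes of nitrate reductase A and formate dehydrogenase N rose (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.48e-05, adjusted p = 0.678 with an estimated correlation). Of 14 genes of iron-sulphur cluster assembly 6 fell (8 adjusted over the list alone, camera adjusted p = 1.45e-07, adjusted p = 0.5 with an estimated correlation). One of them was hscA, a chaperone gene of that pathway (log2 change -1.32 ± 0.18, adjusted p = 0.00398). Of 22 general stress (RpoS) genes 3 rose (10 adjusted over the list alone, camera adjusted p = 1.82e-07, adjusted p = 0.716 with an estimated correlation), a call lost (adjusted p = 0.231 without wild type anoxic propionate replicate 1). Of 16 TCA cycle genes 3 fell (3 adjusted over the list alone, camera adjusted p = 1.08e-05, adjusted p = 0.716 with an estimated correlation), a call lost as well (adjusted p = 0.0913 without wild type anoxic propionate replicate 2).

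With oxygen, propionate raised genes of the TCA cycle, sulphate assimilation and acid resistance in the wild type and lowered those of nitrate reductase A by the preset list test. None of these 4 lists passed with an estimated correlation (adjusted p = 0.106, 0.307, 0.0707 and 0.0707). Succinate dehydrogenase genes sdhA and sdhD rose, sdhA to 2941 ± 439 against 362 ± 0.85 CPM (log2 change 3.02 ± 0.46, adjusted p = 0.0027) and sdhD by a log2 change 3.33 ± 0.48, adjusted p = 0.002. Acid resistance genes hdeD, hdeB and hdeA rose too. For hdeD the level was 52 ± 0.677 against 2.68 ± 0.895 CPM (log2 change 4.19 ± 0.31, adjusted p = 8.94e-06), and hdeB and hdeA had log2 changes of 3.13 ± 0.30 and 2.77 ± 0.34. Other rises were those of tsuA, for a thiosulphate transporter (log2 change 4.09 ± 0.58), and lldP, for lactate uptake (log2 change 2.50 ± 0.28). Nitrate reductase genes narH and narG and the nitrate transporter gene narK fell. Their log2 changes were -4.00 ± 0.53, -3.64 ± 0.52 and -3.96 ± 0.43, with narH at 14 ± 8.6 against 221 ± 74.5 CPM (adjusted p = 0.00132). The gene ndh, of the NADH dehydrogenase that pumps no protons, fell as well (log2 change -2.53 ± 0.28, adjusted p = 2.14e-04). Neither prpB (2219 ± 44.9 against 779 ± 85 CPM, adjusted p = 0.18) nor prpC (2314 ± 29.1 against 769.8 ± 113 CPM, adjusted p = 0.155) passed in the fit to all libraries. A fit without both wild type anoxic propionate libraries, chosen after the data were seen, called prpC (log2 change 1.57 ± 0.28, adjusted p = 0.00276) and prpB (1.49 ± 0.42, adjusted p = 0.0454) as higher. It also called prpD (log2 change 0.96 ± 0.29, adjusted p = 0.0459). Of the 5 prp genes in the fit to all libraries 0 rose (0 adjusted over the list alone, camera adjusted p = 0.042, adjusted p = 0.429 with an estimated correlation), and the call of the list ended without 2 libraries (adjusted p = 0.0564 without wild type oxic glycerol replicate 1, 0.062 without wild type oxic propionate replicate 2).

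By list, 13 of 16 TCA cycle genes rose in the oxic wild type (16 adjusted over the list alone, camera adjusted p = 2.14e-20, adjusted p = 0.106 with an estimated correlation). Of 13 tested acid resistance (Gad) genes 7 rose (10 adjusted over the list alone, camera adjusted p = 2.48e-15, adjusted p = 0.0707 with an estimated correlation). Of 12 sulphate assimilation genes 7 rose (11 adjusted over the list alone, camera adjusted p = 1.49e-10, adjusted p = 0.307 with an estimated correlation). Of 11 genes of the glyoxylate bypass and glycolate use 6 rose (9 adjusted over the list alone, camera adjusted p = 9.08e-08, adjusted p = 0.0707 with an estimated correlation). Of 10 genes of nitrate reductase A and formate dehydrogenase N 6 fell (8 adjusted over the list alone, camera adjusted p = 7.04e-15, adjusted p = 0.0707 with an estimated correlation). Of 17 heat shock genes 10 fell (11 adjusted over the list alone, camera adjusted p = 1.51e-11, adjusted p = 0.0829 with an estimated correlation), among them the chaperone genes groL (log2 change -1.29 ± 0.21, adjusted p = 0.0035) and htpG (log2 change -1.06 ± 0.15, adjusted p = 0.0019).

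In all, propionate changed 305 genes in the oxic wild type, 196 higher and 109 lower. The count became 48 and 90 without wild type oxic glycerol replicates 1 and 2, and 76 and 150 without wild type oxic propionate replicates 1 and 2. It was 785 with the compared groups alone and 481 without both wild type anoxic propionate libraries, a fit chosen after the data were seen. The sulphate uptake gene cysP rose most (log2 change 4.32 ± 0.81, 519.5 ± 186 against 25.7 ± 5.88 CPM, adjusted p = 0.00717). Its call ended when either wild type oxic glycerol library was left out, which leaves 1 library in that group.

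In the mutant, propionate raised the prp genes with and without oxygen. Without oxygen prpE rose (log2 change 4.59 ± 0.52, 217 ± 75.1 against 9.11 ± 1.8 CPM, adjusted p = 0.00181). In the same cells prpB, prpC and prpD had log2 changes of 5.90 ± 0.90, 5.92 ± 0.96 and 6.21 ± 0.91. With oxygen prpE rose (log2 change 6.64 ± 0.58, 502 ± 71.9 against 4.53 ± 3.45 CPM, adjusted p = 2.01e-04), and prpB and prpD had log2 changes of 6.84 ± 1.01 and 6.69 ± 0.89. Of the 5 genes of the methylcitrate cycle list, 4 rose without oxygen (4 adjusted over the list alone, camera adjusted p = 2.89e-17, adjusted p = 0.0246 with an estimated correlation). With oxygen 4 rose as well (4 adjusted over the list alone, camera adjusted p = 2.23e-21, adjusted p = 0.0134 with an estimated correlation). The gene zinT, for a periplasmic zinc-binding protein, fell without oxygen (log2 change -2.79 ± 0.24, 52 ± 6.09 against 359 ± 39.3 CPM, adjusted p = 1.13e-04). With oxygen narK fell (log2 change -2.19 ± 0.29, 67.4 ± 17.8 against 308 ± 118 CPM, adjusted p = 0.00492) and putA, of proline breakdown, rose (log2 change 2.20 ± 0.29, 88.7 ± 30.7 against 19 ± 1.73 CPM, adjusted p = 0.00492). These calls in the mutant were few, 11 genes without oxygen (7 higher, 4 lower) and 16 with oxygen (14 higher, 2 lower). Without oxygen the count became 1 without either mutant anoxic glycerol library, and 19 and 3 without mutant anoxic propionate replicates 1 and 2. Calls of prpB, prpC and prpD there ended without either of these glycerol libraries and without propionate replicate 2 (adjusted p from 0.107 to 0.339). The call of prpE ended without glycerol replicates 1 and 2 (adjusted p = 0.122 and 0.0507), while that of zinT was kept. With oxygen the count became 2 and 1 without mutant oxic glycerol replicates 1 and 2, and 43 and 5 without mutant oxic propionate replicates 1 and 2. Calls of prpB, prpC, prpD and putA ended without either of these glycerol libraries (adjusted p from 0.106 to 0.443). The call of prpC also ended without propionate replicate 2 (adjusted p = 0.0678) and that of narK without glycerol replicate 2 (adjusted p = 0.106), while that of prpE was kept. The compared groups alone gave 5 and 32 calls without and with oxygen, and DESeq2 on all libraries gave 52 and 26. A fit without both wild type anoxic propionate libraries, chosen after the data were seen, gave 76 and 70.

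**Figure D2:**
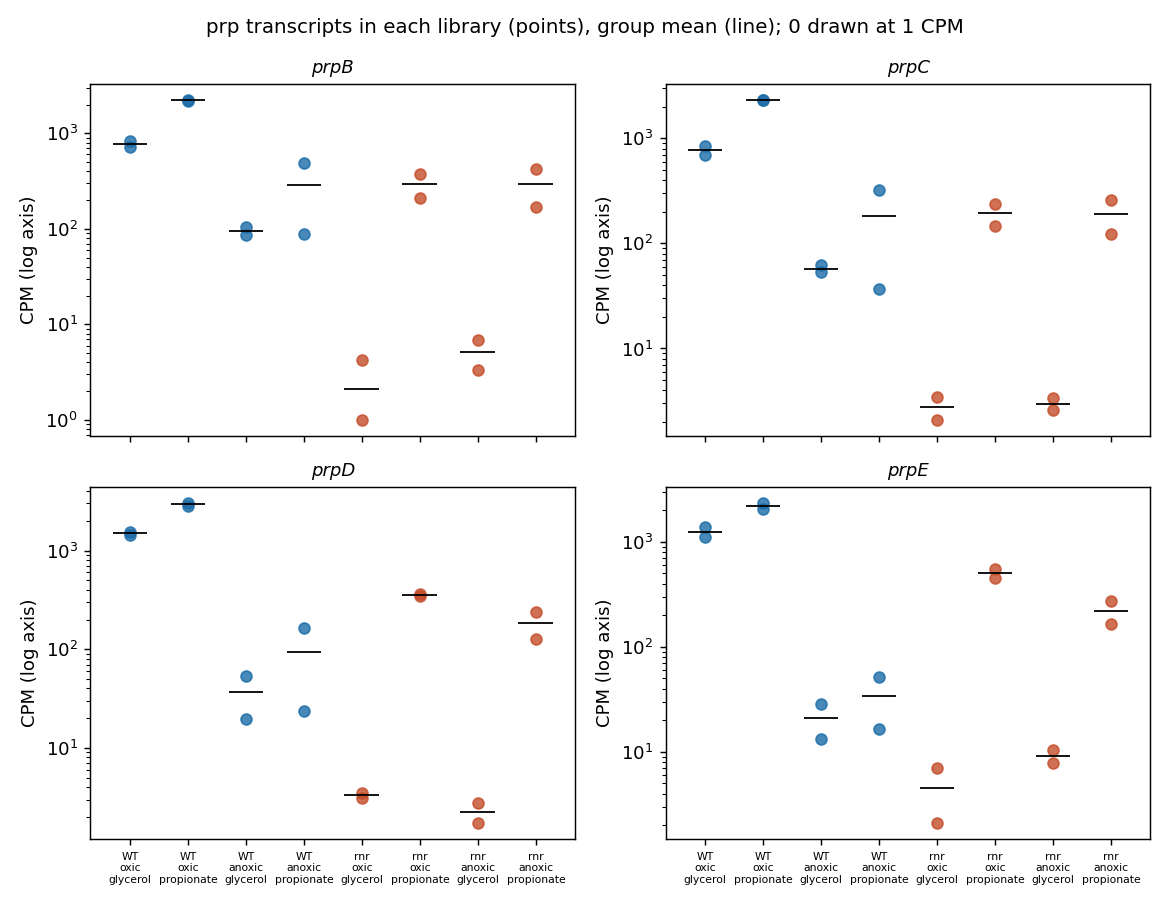
Level of the 4 genes prpB, prpC, prpD and prpE in CPM on a log axis, 1 point per library and a line at each group mean, wild type in blue and mutant in red, with 0 drawn at 1 CPM. Mutant libraries lie at 0 to 10.4 CPM in glycerol and 123 to 553 CPM in propionate, while wild type oxic libraries are high in both media.

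The difference between genotypes in the response to propionate was tested directly. With oxygen it passed for 44 genes, 20 higher and 24 lower in the mutant, with prpE at a log2 change 5.82 ± 0.70, adjusted p = 0.00232. There prpE went from 1248 ± 205 to 2204 ± 201 CPM in the wild type and from 4.53 ± 3.45 to 502 ± 71.9 CPM in the mutant. The mutant thus had the larger ratio, from a lower start and to a lower level. Without oxygen the difference passed for 38 genes, 18 higher and 20 lower, with prpE at a log2 change 3.85 ± 0.74, adjusted p = 0.0313. The latter call of prpE ended without wild type anoxic glycerol replicates 1 and 2 (adjusted p = 0.157 and 0.0628) and mutant anoxic glycerol replicates 1 and 2 (adjusted p = 0.171 and 0.097). It also ended without mutant anoxic propionate replicate 2 (adjusted p = 0.123). The response of the wild type to propionate differed with oxygen for 243 genes, 105 higher and 138 lower without oxygen. Among them were narH (log2 change 6.52 ± 0.68, adjusted p = 4.11e-04) and tyrP (log2 change -5.04 ± 0.47, adjusted p = 2.52e-04). The count of 44 became 4 and 6 without wild type oxic glycerol replicates 1 and 2, and 6 and 16 without wild type oxic propionate replicates 1 and 2. It became 7 and 5 without mutant oxic glycerol replicates 1 and 2, and 124 and 7 without mutant oxic propionate replicates 1 and 2. The count of 38 became 15 and 4 without wild type anoxic glycerol replicates 1 and 2, and 224 and 233 without wild type anoxic propionate replicates 1 and 2. It became 3 and 2 without mutant anoxic glycerol replicates 1 and 2, and 89 and 5 without mutant anoxic propionate replicates 1 and 2. The count of 243 became 126 and 104 without wild type anoxic glycerol replicates 1 and 2, and 73 and 126 without wild type oxic glycerol replicates 1 and 2. It became 484 and 554 without wild type anoxic propionate replicates 1 and 2, and 82 without wild type oxic propionate replicate 1. With the compared groups alone 0 genes passed for propionate by genotype without oxygen, with 372 at an unadjusted p under 0.05, so each of the 38 calls ended there. That fit gave 242 genes with oxygen and 146 for the wild type by oxygen, while DESeq2 on all libraries gave 110 and 119 for propionate by genotype without and with oxygen.

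Anoxic growth on nitrate, against oxic growth without it, changed 1646 genes in wild type cells in glycerol, 750 higher and 896 lower. Among the neighbouring genes yoaG and yeaR, yoaG was at least 60.4-fold higher (83.1 ± 3.51 against 0 ± 0 CPM), against a floor of 3 counts over the group. The other, yeaR, rose by a log2 change 5.64 ± 0.29, adjusted p = 2.38e-08. Methionine synthesis gene metF rose (log2 change 5.41 ± 0.76, 2392 ± 72.1 against 56.2 ± 2.61 CPM, adjusted p = 1.28e-04), as did tyrP (log2 change 5.52 ± 0.33, adjusted p = 1.03e-07). The iron-sulphur regulator gene iscR rose (log2 change 4.16 ± 0.21, 1821 ± 236 against 102 ± 4.19 CPM, adjusted p = 2.38e-08), as did ytfE, for a repair protein of iron centres (log2 change 6.20 ± 1.15, adjusted p = 9.41e-04). Pseudouridine use genes psuG and psuT fell, psuG to 15.2 ± 10.3 against 4891 ± 176 CPM (log2 change -8.31 ± 0.50, adjusted p = 1.19e-07) and psuT by a log2 change -6.42 ± 0.25, adjusted p = 4.36e-09. The galactose-binding protein gene mglB fell (log2 change -6.12 ± 0.42, adjusted p = 2.88e-07), as did prpE (log2 change -5.91 ± 0.51, adjusted p = 2.17e-06). Glycerol kinase gene glpK fell (log2 change -5.21 ± 0.33, 236 ± 61.2 against 8728 ± 147 CPM, adjusted p = 1.41e-07).

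By list, 14 of 15 tested maltose and galactose transport genes fell in wild type glycerol (14 adjusted over the list alone, camera adjusted p = 5.81e-19, adjusted p = 0.0129 with an estimated correlation). Of 14 genes of glycerol uptake and oxidation 9 fell and 2 rose (2 higher and 9 lower adjusted over the list alone, camera adjusted p = 2.76e-09, adjusted p = 0.126 with an estimated correlation). Of 5 prp genes 4 fell (4 adjusted over the list alone, camera adjusted p = 0.00587, adjusted p = 0.382 with an estimated correlation). Of 12 methionine synthesis genes 11 rose and 1 fell (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.26e-10, adjusted p = 0.126 with an estimated correlation). All 12 sulphate assimilation genes rose (12 adjusted over the list alone, camera adjusted p = 2.49e-05, adjusted p = 0.481 with an estimated correlation). Of 11 arginine synthesis genes 10 rose (10 adjusted over the list alone, camera adjusted p = 5.89e-08, adjusted p = 0.352 with an estimated correlation), and of 54 ribosomal protein genes 44 rose (46 adjusted over the list alone, camera adjusted p = 3.21e-07, adjusted p = 0.527 with an estimated correlation). Of 14 iron-sulphur assembly genes 8 rose and 5 fell (8 higher and 6 lower adjusted over the list alone, camera adjusted p = 7.95e-09, adjusted p = 0.126 with an estimated correlation). Of 14 genes of fumarate and DMSO respiration 9 fell (9 adjusted over the list alone, camera adjusted p = 5.96e-05, adjusted p = 0.382 with an estimated correlation). Fumarate reductase gene frdA was among them (log2 change -4.67 ± 0.33, adjusted p = 2.94e-07).

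In propionate the same contrast changed 1282 wild type genes, 552 higher and 730 lower. Formate dehydrogenase N gene fdnH rose (log2 change 6.68 ± 0.65, 442 ± 314 against 4.28 ± 1.84 CPM, adjusted p = 7.24e-06), as did narI of nitrate reductase A (log2 change 6.22 ± 0.50, 282 ± 66.8 against 3.59 ± 1.92 CPM, adjusted p = 1.29e-06). The genes yeaR (log2 change 6.92 ± 0.34, adjusted p = 2.17e-08) and iscR (log2 change 3.46 ± 0.21, adjusted p = 1.11e-07) rose as well. Acetyl-CoA synthetase gene acs fell (log2 change -6.57 ± 0.45, 16.3 ± 7.52 against 1525 ± 35.2 CPM, adjusted p = 3.41e-07), and so did prpE (log2 change -5.98 ± 0.49, 33.8 ± 24.5 against 2204 ± 201 CPM, adjusted p = 1.84e-06). Further falls were those of psuK, of pseudouridine use (log2 change -8.67 ± 0.36, adjusted p = 2.17e-08), and sucC, of succinyl-CoA synthetase (log2 change -3.91 ± 0.29, adjusted p = 5.14e-07).

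By list in wild type propionate, 8 of 10 genes of nitrate reductase A and formate dehydrogenase N rose (8 adjusted over the list alone, camera adjusted p = 2.54e-09, adjusted p = 0.129 with an estimated correlation). Methionine synthesis rose in 11 of 12 genes, with 1 lower (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.30e-14, adjusted p = 0.0613 with an estimated correlation). Of 15 tested maltose and galactose transport genes 14 fell (15 adjusted over the list alone, camera adjusted p = 1.08e-22, adjusted p = 0.00505 with an estimated correlation). Of 16 TCA cycle genes 14 fell (15 adjusted over the list alone, camera adjusted p = 6.16e-09, adjusted p = 0.231 with an estimated correlation). All 13 nuo genes of NADH dehydrogenase I fell (13 adjusted over the list alone, camera adjusted p = 1.55e-04, adjusted p = 0.338 with an estimated correlation), and so did all 9 ATP synthase genes (9 adjusted over the list alone, camera adjusted p = 6.40e-05, adjusted p = 0.239 with an estimated correlation). The count of 1282 became 850 without wild type oxic propionate replicate 2 and 614 with the compared groups alone.

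In the mutant, anoxic growth on nitrate against oxic growth changed 1596 genes in glycerol (811 higher, 785 lower) and 1739 in propionate (854 higher, 885 lower). Formate dehydrogenase N gene fdnH rose in glycerol (log2 change 6.11 ± 0.53, 2102 ± 77.5 against 30.2 ± 2.72 CPM, adjusted p = 2.91e-06) and in propionate (log2 change 6.60 ± 0.55, adjusted p = 1.76e-06). The gene yeaR rose in both media too (6.65 ± 0.34 and 6.57 ± 0.32 on the log2 scale). Outer membrane protein gene ompW fell in glycerol (log2 change -6.00 ± 0.50, 6.26 ± 0.934 against 400.3 ± 125 CPM, adjusted p = 2.32e-06). In propionate tdcB, of threonine breakdown, was at least 154-fold lower, with 0 counts in the anoxic libraries. Of 15 tested maltose and galactose transport genes 14 fell in glycerol (14 adjusted over the list alone, camera adjusted p = 4.76e-16, adjusted p = 0.0191 with an estimated correlation). The same number fell in propionate (15 adjusted over the list alone, camera adjusted p = 1.06e-15, adjusted p = 0.013 with an estimated correlation). Of 14 genes of branched-chain amino acid synthesis 13 fell and 1 rose in glycerol (1 higher and 13 lower adjusted over the list alone, camera adjusted p = 1.52e-07, adjusted p = 0.029 with an estimated correlation). In propionate 13 of them fell (13 adjusted over the list alone, camera adjusted p = 8.79e-08, adjusted p = 0.013 with an estimated correlation), and all 14 genes of fumarate and DMSO respiration fell (14 adjusted over the list alone, camera adjusted p = 7.16e-09, adjusted p = 0.262 with an estimated correlation).

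Between genotypes, motility genes were far lower in the mutant in each of the 4 conditions, gene by gene and by the preset list test, though not with an estimated correlation (adjusted p from 0.0631 to 0.18). In anoxic glycerol the flagellin gene fliC was at 69.7 ± 4.37 against 22490 ± 1539 CPM in the wild type (log2 change -8.33 ± 0.76, adjusted p = 9.70e-06), and the chemotaxis kinase gene cheA fell with it (log2 change -8.75 ± 0.57, adjusted p = 4.79e-07). Methionine synthase gene metE fell (log2 change -5.92 ± 0.29, 266 ± 52.7 against 16060 ± 1321 CPM, adjusted p = 6.38e-08). Galactitol uptake gene gatC rose (log2 change 8.20 ± 0.40, 3553 ± 330.5 against 11.9 ± 8.42 CPM, adjusted p = 6.38e-08). Glyoxylate bypass genes aceB and aceA rose, aceB to 12680 ± 861 against 538 ± 144 CPM (log2 change 4.56 ± 0.37, adjusted p = 3.04e-06) and aceA by a log2 change 4.09 ± 0.25, adjusted p = 2.23e-07. Nitrate reductase gene narH (log2 change 4.82 ± 0.47, adjusted p = 1.39e-05) and glutamate decarboxylase gene gadB (log2 change 3.81 ± 0.26, adjusted p = 5.06e-07) rose as well. The outer membrane porin gene nmpC was at least 185-fold higher (255 ± 71.2 against 0 ± 0 CPM). Over all libraries it had 1 count in the wild type against 9604 in the mutant, and it lies in a run of 7 neighbouring genes near 0 in the wild type. A stretch missing from the wild type and a change in expression cannot be told apart for nmpC, here or in the other conditions. In all 991 genes changed, 557 higher and 434 lower.

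By list in anoxic glycerol, all 44 genes of flagella and chemotaxis fell (median log2 change -6.77, 44 adjusted over the list alone, camera adjusted p = 3.75e-61, adjusted p = 0.0631 with an estimated correlation). Of 12 methionine synthesis genes 11 fell (11 adjusted over the list alone, camera adjusted p = 2.05e-26, adjusted p = 0.0214 with an estimated correlation). Of 14 genes of branched-chain amino acid synthesis 11 fell (12 adjusted over the list alone, camera adjusted p = 2.48e-08, adjusted p = 0.0214 with an estimated correlation). Of 14 iron-sulphur assembly genes 13 fell (13 adjusted over the list alone, camera adjusted p = 5.79e-09, adjusted p = 0.0631 with an estimated correlation). Of 11 glyoxylate bypass and glycolate genes 8 rose (9 adjusted over the list alone, camera adjusted p = 5.58e-10, adjusted p = 0.0268 with an estimated correlation). Of 10 genes of nitrate reductase A and formate dehydrogenase N 9 rose (9 adjusted over the list alone, camera adjusted p = 1.76e-10, adjusted p = 0.0631 with an estimated correlation). Of 13 tested acid resistance genes 8 rose (8 adjusted over the list alone, camera adjusted p = 2.61e-10, adjusted p = 0.088 with an estimated correlation). The count of 991 became 527 without wild type anoxic glycerol replicate 1 and 511 without mutant anoxic glycerol replicate 1.

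In anoxic propionate 1191 genes differed, 666 higher and 525 lower in the mutant. The levels of fliC were 51 ± 0.874 against 26730 ± 27990 CPM (log2 change -9.03 ± 0.78, adjusted p = 6.42e-06), and those of metE were 334 ± 101 against 16110 ± 550.1 CPM (log2 change -5.59 ± 0.29, adjusted p = 7.11e-08). Among the rises were gatC (log2 change 7.40 ± 0.39, 2841 ± 490.1 against 16.4 ± 5.71 CPM, adjusted p = 7.11e-08), tabA (log2 change 4.81 ± 0.25, adjusted p = 7.11e-08) and hdeA (log2 change 4.33 ± 0.34, adjusted p = 1.86e-06). The glyoxylate bypass gene aceA (log2 change 4.27 ± 0.25, adjusted p = 2.92e-07) and the co-chaperonin gene groS (log2 change 2.75 ± 0.21, adjusted p = 1.21e-06) rose too. By list, 43 of 44 flagella and chemotaxis genes fell (43 adjusted over the list alone, camera adjusted p = 3.36e-55, adjusted p = 0.101 with an estimated correlation). All 12 methionine synthesis genes fell (12 adjusted over the list alone, camera adjusted p = 2.23e-24, adjusted p = 0.0299 with an estimated correlation). Of 14 branched-chain synthesis genes 9 fell (9 adjusted over the list alone, camera adjusted p = 5.37e-06, adjusted p = 0.0499 with an estimated correlation). Of 13 tested acid resistance genes 9 rose (9 adjusted over the list alone, camera adjusted p = 2.65e-10, adjusted p = 0.101 with an estimated correlation). Of 17 heat shock genes 13 rose and 1 fell (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.60e-07, adjusted p = 0.155 with an estimated correlation). The count of 1191 became 779 without mutant anoxic propionate replicate 2 and 150 with the compared groups alone.

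In oxic glycerol 743 genes differed, 339 higher and 404 lower in the mutant. The prp genes fell, prpD to 3.31 ± 0.248 against 1495 ± 88.7 CPM (log2 change -8.76 ± 0.90, adjusted p = 2.50e-05), with prpB and prpE at log2 changes of -8.24 ± 1.01 and -7.95 ± 0.59. Pseudouridine use gene psuK fell (log2 change -8.91 ± 0.36, 4.36 ± 1.73 against 2250 ± 39.9 CPM, adjusted p = 2.05e-08), and fliC fell (log2 change -9.28 ± 0.79, 75.5 ± 4.71 against 46960 ± 938 CPM, adjusted p = 6.22e-06). An iron-catecholate receptor gene, fiu, fell (log2 change -4.87 ± 0.52, 18.1 ± 0.98 against 530 ± 45 CPM, adjusted p = 2.74e-05). Galactitol gene gatC rose (log2 change 8.27 ± 0.39, 8271 ± 585 against 26.4 ± 8.36 CPM, adjusted p = 2.05e-08), as did hdeD (log2 change 4.50 ± 0.30, adjusted p = 4.46e-07) and aceB (log2 change 4.14 ± 0.37, adjusted p = 5.38e-06). Periplasmic nitrate reductase gene napA rose (log2 change 2.62 ± 0.27, adjusted p = 1.47e-05). The porin gene nmpC had 4427 counts against 1 in the wild type, a ratio of 4040 (counting interval 725 to 160000).

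By list in oxic glycerol, all 44 flagella and chemotaxis genes fell (44 adjusted over the list alone, camera adjusted p = 1.15e-72, adjusted p = 0.18 with an estimated correlation). Of 5 prp genes 4 fell (4 adjusted over the list alone, camera adjusted p = 2.03e-07, adjusted p = 0.18 with an estimated correlation). Of 33 tested iron uptake (Fur) genes 24 fell (27 adjusted over the list alone, camera adjusted p = 1.98e-18, adjusted p = 0.2 with an estimated correlation). Of 13 tested acid resistance genes 11 rose (12 adjusted over the list alone, camera adjusted p = 4.97e-11, adjusted p = 0.18 with an estimated correlation). Of 12 sulphate assimilation genes 9 rose (9 adjusted over the list alone, camera adjusted p = 5.23e-04, adjusted p = 0.847 with an estimated correlation). The count of 743 became 353 and 462 without wild type oxic glycerol replicates 1 and 2, and 437 and 383 without mutant oxic glycerol replicates 1 and 2. It was 1325 with the compared groups alone.

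In oxic propionate 758 genes differed, 337 higher and 421 lower in the mutant. Flagellin gene fliC fell (log2 change -9.57 ± 0.80, 75.5 ± 0.153 against 57570 ± 3194 CPM, adjusted p = 5.55e-06), psuG fell (log2 change -8.73 ± 0.51, adjusted p = 2.07e-07), and araA was at least 17.6-fold lower. Galactitol gene gatC rose (log2 change 8.76 ± 0.40, 10460 ± 391 against 24 ± 2.42 CPM, adjusted p = 1.53e-08), and nmpC was at least 987-fold higher (1547 ± 182 against 0 ± 0 CPM). Genes of nitrate and nitrite reduction rose, with napA at 305 ± 65.1 against 17.8 ± 1.47 CPM (log2 change 4.09 ± 0.32, adjusted p = 2.48e-06), and narK and nirB at log2 changes of 3.40 ± 0.44 and 4.04 ± 0.65. The methylcitrate synthase gene prpC was at 194 ± 65.1 against 2314 ± 29.1 CPM (log2 change -3.58 ± 0.68, adjusted p = 0.00262). By list, all 44 flagella and chemotaxis genes fell (44 adjusted over the list alone, camera adjusted p = 7.06e-72, adjusted p = 0.114 with an estimated correlation). All 5 prp genes fell (5 adjusted over the list alone, camera adjusted p = 0.00178, adjusted p = 0.379 with an estimated correlation). Of 33 tested iron uptake genes 22 fell and 1 rose (1 higher and 23 lower adjusted over the list alone, camera adjusted p = 6.72e-12, adjusted p = 0.379 with an estimated correlation). Of 10 genes of nitrate reductase A and formate dehydrogenase N 6 rose (7 adjusted over the list alone, camera adjusted p = 7.76e-05, adjusted p = 0.379 with an estimated correlation). Of 9 tested nitrite reductase genes 6 rose (7 adjusted over the list alone, camera adjusted p = 3.45e-04, adjusted p = 0.404 with an estimated correlation). The count of 758 became 363 without wild type oxic propionate replicate 1 and 463 without mutant oxic propionate replicate 2.

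**Figure D3:**
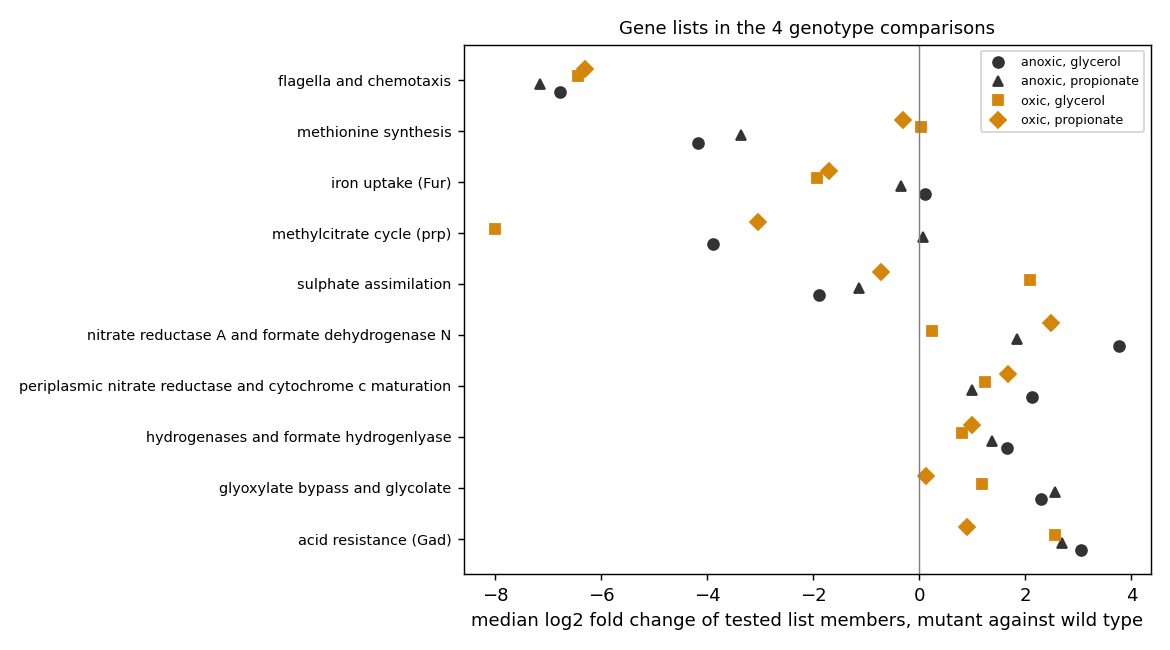
Median log2 fold change of the tested members of 10 gene lists, mutant against wild type, in each of the 4 conditions (anoxic in black, oxic in orange). Flagella and chemotaxis lie far below 0 in each condition, and methionine synthesis lies below -3 in the anoxic conditions and near 0 in the oxic ones; with napD, at 0 counts in the anoxic mutant in propionate, set at its bound, the periplasmic nitrate reductase median there is 0.81 in place of 0.99.

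Over the mean of the 4 conditions 1532 genes differed between the genotypes, 830 higher and 702 lower in the mutant. Flagellin gene fliC was lower (log2 change -9.05 ± 0.39, adjusted p = 3.28e-09) and galactitol gene gatC higher (log2 change 8.16 ± 0.20, adjusted p = 1.16e-11). All 44 flagella and chemotaxis genes fell (44 adjusted over the list alone, camera adjusted p = 4.98e-105, adjusted p = 0.0704 with an estimated correlation). Of 13 tested acid resistance genes 12 rose (12 adjusted over the list alone, camera adjusted p = 2.95e-12, adjusted p = 0.0895 with an estimated correlation). All 10 genes of nitrate reductase A and formate dehydrogenase N rose (10 adjusted over the list alone, camera adjusted p = 2.96e-07, adjusted p = 0.205 with an estimated correlation).

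In glycerol the genotype difference depended on oxygen for 679 genes, 392 higher and 287 lower without oxygen. Among them were metE (log2 change -6.81 ± 0.37, adjusted p = 3.82e-07) and prpE (log2 change 6.75 ± 0.88, adjusted p = 4.49e-04). In that test 11 of 12 methionine synthesis genes were lower (11 adjusted over the list alone, camera adjusted p = 1.71e-29, adjusted p = 0.0169 with an estimated correlation). Of 33 tested iron uptake genes 22 were higher (26 adjusted over the list alone, camera adjusted p = 2.22e-15, adjusted p = 0.159 with an estimated correlation). The count of 679 became 405 without wild type anoxic glycerol replicate 1 and 409 without wild type oxic glycerol replicate 1. It became 423 and 434 without mutant anoxic glycerol replicates 1 and 2, 434 and 423 without mutant oxic glycerol replicates 1 and 2, and 1230 with the compared groups alone. Of all list tests over the 17 comparisons, 273 passed with the preset correlation and 14 with an estimated one.

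**Figure D4:**
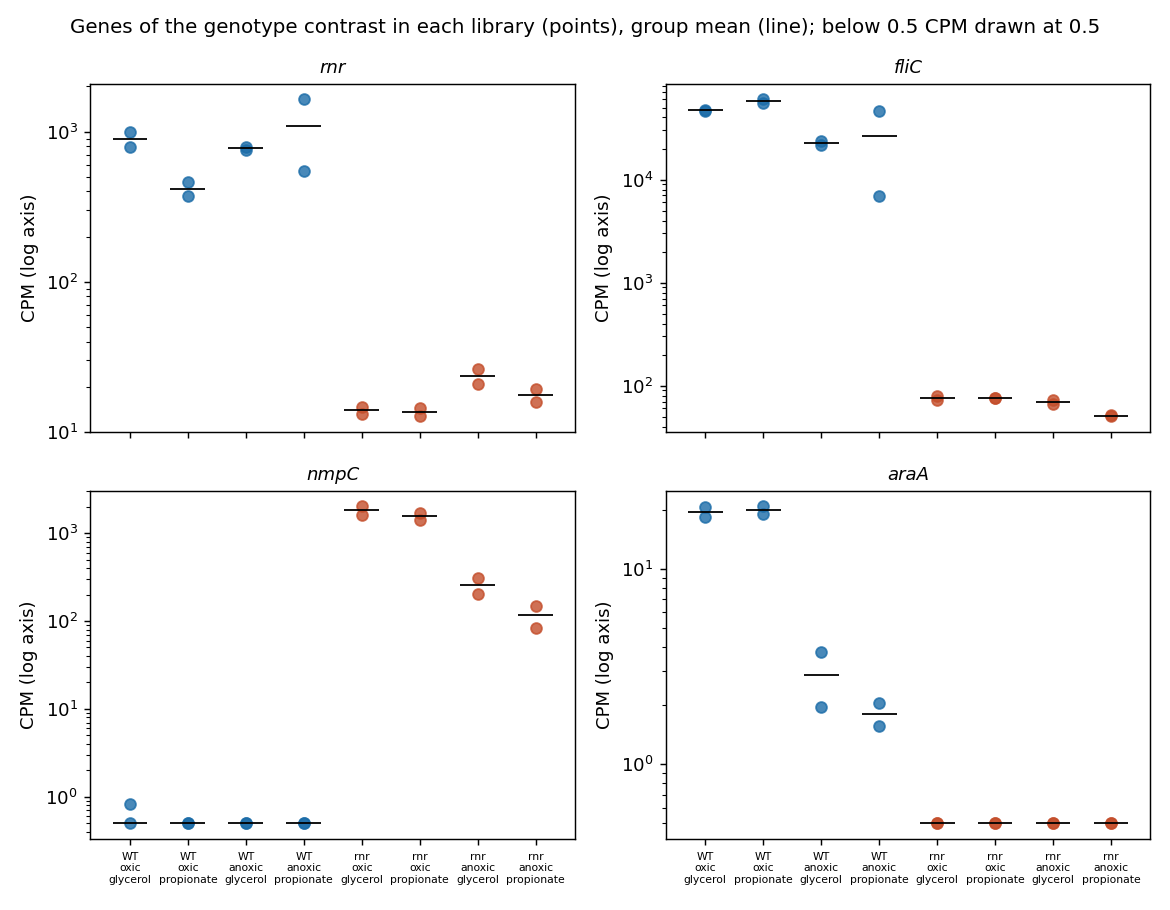
Level of rnr, fliC, nmpC and araA in CPM on a log axis, 1 point per library and a line at each group mean, with values below 0.5 CPM drawn at 0.5. Wild type is blue and mutant red, and each of the 4 genes separates all 8 wild type from all 8 mutant libraries.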

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

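Of the tests in this part, the search for runs of neighbouring genes, the test for separate batches and the test for oxygen in replicate 1 were chosen only after the result was seen, while the exchange of genotype labels was fixed before. The bounds of the tests for missing propionate and for cooling were set before those tests were run. Both tests name a pair of libraries whose distance had by then been seen.

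In the wild type the response to propionate differed between anoxic and oxic cultures by the interaction test for 243 genes. Anoxic minus oxic, the log2 response was higher for narH (6.52), narJ (5.51) and narI (4.81) of nitrate reductase A, for ibpB (6.82), a small heat shock chaperone gene, and for nirD (4.70) of nitrite reductase. It was lower for tyrP (-5.04), for ymgC (-5.39), ymgA (-4.83) and ycgZ (-4.69), neighbouring small genes, and for cysP (-4.14) of sulphate uptake. The calls of narH, narJ, narI and tyrP were kept without any 1 of the 8 libraries compared. That of ycgZ ended without wild type oxic propionate replicate 1 (adjusted p = 0.132), and those of ibpB, nirD, ymgC, ymgA and cysP each ended without any of 5 to 7 libraries, with adjusted p from 0.0517 to 0.892, the last for ymgC without wild type oxic propionate replicate 1 (log2 difference -0.25). For ibpB these were every library of the 4 groups except the wild type anoxic propionate pair, for nirD every one except wild type anoxic propionate replicate 1, and for cysP every one except wild type anoxic glycerol replicate 2 and oxic propionate replicate 2. For ymgC and ymgA they were the 4 wild type glycerol libraries and oxic propionate replicate 1. The count of 243 became 126 and 104 without wild type anoxic glycerol replicates 1 and 2, 73 and 126 without oxic glycerol replicates 1 and 2, 484 and 554 without anoxic propionate replicates 1 and 2, and 82 without oxic propionate replicate 1, and was 146 with the compared groups alone.

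The response to propionate differed between mutant and wild type for 38 genes without oxygen. Mutant minus wild type, it was higher for tyrP (3.87), prpE (3.85), pyrE (3.09), argA (2.28), of arginine synthesis, and potH (2.07), of putrescine uptake, and lower for mlrA (-3.08), pspB (-3.07), of the phage shock response, nrfE (-2.99), zinT (-2.56) and narJ (-2.50). With the compared groups alone 0 genes passed, so all of these calls ended there (372 genes at an unadjusted p under 0.05). In the fit to all libraries those of tyrP and zinT were kept without any 1 of the 8 libraries, and the others ended without either mutant anoxic glycerol library and without mutant anoxic propionate replicate 2 (adjusted p from 0.084 to 0.171). They also ended without wild type anoxic glycerol replicate 1, except argA, and without its replicate 2, except narJ (adjusted p from 0.0511 to 0.157), and potH ended without mutant anoxic propionate replicate 1 (adjusted p = 0.0703). The count of 38 became 15 and 4 without wild type anoxic glycerol replicates 1 and 2, 224 and 233 without wild type anoxic propionate replicates 1 and 2, 3 and 2 without mutant anoxic glycerol replicates 1 and 2, and 89 and 5 without mutant anoxic propionate replicates 1 and 2.

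With oxygen the same difference passed for 44 genes. It was higher in the mutant for prpE (5.82), prpD (5.71), nirD (4.83), narH (3.24) and punC (2.84), which encodes a purine nucleoside transporter, and lower for cysP (-5.24), cysJ (-4.12), tsuA (-3.99), hdeD (-3.92) and lldP (-2.74). These values compare ratios, not levels. From glycerol to propionate prpD went from 1495 to 2945 CPM in the wild type and from 3.31 to 356 in the mutant. For prpE it was 1248 to 2204 CPM and 4.53 to 502 CPM, so both genes stayed lower in the mutant. The calls of prpE, punC and hdeD were kept without any 1 of the 8 libraries. Those of prpD, nirD, narH, cysP, cysJ and tsuA ended without each of the 8 except mutant oxic propionate replicate 1 (adjusted p from 0.0549 to 0.217), and that of lldP without wild type oxic glycerol replicates 1 and 2, wild type oxic propionate replicate 1, mutant oxic glycerol replicate 1 and mutant oxic propionate replicate 2 (adjusted p from 0.0528 to 0.0935). The count of 44 became 4 and 6 without wild type oxic glycerol replicates 1 and 2, 6 and 16 without wild type oxic propionate replicates 1 and 2, 7 and 5 without mutant oxic glycerol replicates 1 and 2, and 124 and 7 without mutant oxic propionate replicates 1 and 2, and was 242 with the compared groups alone.

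In glycerol the genotype difference changed with oxygen for 679 genes. Anoxic minus oxic, it was higher for prpE (6.75), psuT (5.79), rihB (5.24), a ribonucleoside hydrolase gene, fiu (5.04) and narH (4.89), and lower for metE (-6.81), cysP (-6.40), cysD (-6.07), tauA (-5.55), of taurine uptake, and ariR (-5.42). The call of rihB ended without mutant anoxic glycerol replicate 1 (adjusted p = 0.207). Those of tauA and ariR ended without wild type anoxic glycerol replicate 1, wild type oxic glycerol replicate 1 and either mutant oxic glycerol library, and without mutant anoxic glycerol replicate 1 for tauA and 2 for ariR (adjusted p from 0.0505 to 0.164). In these interaction tests nirD, ymgC, ymgA, ycgZ, rihB, tauA and ariR had 1 to 3 counts in at least 1 group, so their fitted values depend on the prior count of the fit. The count of 679 became 405 without wild type anoxic glycerol replicate 1, 409 without wild type oxic glycerol replicate 1, 423 and 434 without mutant anoxic glycerol replicates 1 and 2, and 434 and 423 without mutant oxic glycerol replicates 1 and 2, and was 1230 with the compared groups alone, where the call of cysD ended.

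The share of reads not aligned, a measure that no gene comparison used, was higher in the wild type than in the mutant by 1.73 percentage points (exact permutation p = 1.55e-04, n = 8 libraries each). Groups of 2 libraries were too small for a test of single outlying libraries.

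The first pattern weighed is the set of 1532 genes that differed between the genotypes over the mean of 4 conditions. Chance alone is unlikely, if the libraries are independent, since 1 of 100 splits with genotype labels exchanged within conditions, the real one, gave as many genes, and the highest of the others gave 862. Only 100 of 648 possible splits were drawn, with the real one always among them, so a share below 1 of 100 could not be reached. For loss of rnr as the only difference between the strains, runs of neighbouring genes were counted. In 3 runs lay 16 neighbours with counts in 1 genotype and at most 3 in the other, against at most 3 genes in 10000 random placements. Random placement breaks up operons and prophages. The test therefore cannot tell a missing stretch of chromosome from neighbours switched off together, and does not decide whether rnr is the only difference. The runs held araB, araA and araD, near 0 in the mutant, and genes from xisD to nmpC and from intZ to yffS, near 0 in the wild type, so a different parent strain, for which BW25113 with its known loss of araBAD, rhaDAB and part of lacZ is a candidate source, may account for part of the pattern. Separate library or sequencing batches cannot be told apart from genotype, since the share of reads not aligned lay on the side of its genotype in 16 of 16 libraries, and an effect of rnr itself stays open as the untested biological explanation.

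The second pattern is the distance between the 2 wild type anoxic propionate libraries. If replicate 1 had grown without propionate, its change from glycerol would be unrelated to that of replicate 2, and the correlation across genes, which are not independent replicates, was 0.089 and 0.1 in the 2 ways of pairing with glycerol libraries, against 0.222 to 0.665 in the other conditions. This value is consistent with that explanation, as are the log2 changes of prpB (-0.11 in replicate 1 and 2.35 in replicate 2), but it leaves unexplained that replicate 1 was above glycerol as far as replicate 2 or farther for narH (2.64 and 2.53), narJ (2.59 and 1.96) and narI (2.02 and 1.53), which passed the test on both libraries, and for fdnH (2.46 and 0.87), which did not (adjusted p = 0.0553). Oxygen in the culture of replicate 1 cannot be told apart from other differences: over 3531 genes replicate 1 minus replicate 2 correlated with the oxic minus anoxic change of the mutant in glycerol at r = 0.319, against at most 0.189 in size in the other 7 pairs, while the 7 anoxia-raised genes of nitrate reductase A and formate dehydrogenase N went the other way, higher in replicate 1 by a median of 0.633 with an SD of 0.736. Cooling of replicate 2 stays open as well: its 7 test genes had a median of 0.194 higher, 5 of 7 above 0. Of the 7, deaD (0.57) and lpxP (1.16) were above all 15 other libraries there, while raiA (-1.46) and pnp (-0.22) were lower than in replicate 1. Outside the test, cspB (3.41), cspF (2.96), cspG (4.31), cspH (3.59), cspI (4.74) and rnr (1.57) were higher in replicate 2, and cspA only slightly (0.22). No biological explanation was tested, since both libraries carry the same labels.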

How the results depend on the processing

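The fit without both wild type anoxic propionate libraries and the one without flagella genes and the runs at 0 were the tests chosen only after the result was seen; all other alternatives were fixed before. Other size factors (RLE), no filter on low counts, and the fit without flagella genes moved no count of calls by over 1.5 times. The replicate block moved none either: over 28 pairs of groups the deviations of equal numbers correlated from -0.265 to 0.222 (median -0.011, 3 over 0.1 and 4 under -0.1), and the labels give no shared origin to equal numbers, so these were not taken to pair the libraries. In the mutant, the changes from glycerol of the 2 propionate libraries agreed better with equal than with crossed numbers (r = 0.413 against 0.222 without oxygen, 0.435 against 0.304 with it). Leaving out rRNA and tRNA genes was not run, since the counts hold 0 such genes. The cause was not tested for any change given here, except that a fit to fewer libraries has fewer degrees of freedom and another estimate of spread.

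DESeq2 called 141 genes for propionate in the anoxic wild type, 52 and 26 in the anoxic and oxic mutant, and 110 and 119 for propionate by genotype without and with oxygen. Only the compared groups gave 0 for propionate in the anoxic wild type (edgeR, 257 at unadjusted p under 0.05) and 785 in the oxic, 5 and 32 in the anoxic and oxic mutant, 614 for oxygen in wild type propionate, 150 and 1325 for genotype in anoxic propionate and oxic glycerol, 146 for propionate by oxygen, 0 and 242 for propionate by genotype without oxygen (edgeR, 372 at unadjusted p under 0.05) and with it, and 1230 for genotype by oxygen. Without both wild type anoxic propionate libraries propionate gave 481 in the oxic wild type, 76 and 70 in the anoxic and oxic mutant, and 175 for propionate by genotype with oxygen. With an estimated correlation 14 of 273 list tests passed.

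Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave these ranges of calls. For propionate, 15 to 397 and 48 to 150 in the anoxic and oxic wild type, and 1 to 19 and 1 to 43 in the mutant. For oxygen in wild type propionate, 850 to 1604. For genotype, 511 to 710 in anoxic glycerol, 779 to 1173 in anoxic propionate, 353 to 462 in oxic glycerol and 363 to 575 in oxic propionate. For propionate by oxygen 73 to 554, for propionate by genotype 2 to 233 and 4 to 124 without and with oxygen, and for genotype by oxygen 405 to 525. Among named genes that passed in either fit, signs reversed for ibpB (genotype, anoxic propionate, -4.34 to 0.26, the latter without wild type replicate 1), cspG (oxygen, wild type propionate, -0.39 to 3.95, the former without anoxic replicate 2) and prpC (propionate by oxygen, -2.23 to 0.89, the former without anoxic propionate replicate 2).

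Of the values of named genes, 7167 of 8888 kept their side of the threshold when 1 library was left out, and their sign where either fit passed. Of the rest, 1705 no longer passed and 3 reversed. Signs of genes that passed in neither fit were not compared. By the same rule 1181 of 1417 values were kept with the compared groups alone and 1538 of 1584 with DESeq2. With RLE 1594 of 1613 were kept, with no filter 1546 of 1613 and with the replicate block 1556 of 1613. Depth limits genes near the floor of 3 counts, which is 1.69 to 3.48 CPM, and intervals and floors cover counting error only.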

Other observations

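Of the tests in this part, both on the source of the prp transcripts were chosen only after the result was seen.

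Further list results are given here. In the mutant in glycerol, anoxic growth on nitrate raised 25 and lowered 3 of 33 tested iron uptake (Fur) genes (27 higher and 3 lower adjusted over the list alone, camera adjusted p = 3.08e-07, adjusted p = 0.55 with an estimated correlation), and 10 of 11 arginine synthesis genes rose (10 adjusted over the list alone, camera adjusted p = 3.97e-04, adjusted p = 0.573 with an estimated correlation). In wild type propionate, 6 of 8 genes of nitric oxide stress rose without oxygen (6 adjusted over the list alone, camera adjusted p = 0.00489, adjusted p = 0.268 with an estimated correlation), among them hcp, the hybrid cluster protein gene, at log2 change 4.21 ± 0.67, adjusted p = 3.89e-04. All 7 genes of mixed-acid fermentation fell without oxygen in wild type glycerol (7 adjusted over the list alone, camera adjusted p = 9.32e-04, adjusted p = 0.479 with an estimated correlation), where nitrate was present. Of 21 tested hydrogenase and formate hydrogenlyase genes 17 were higher in the mutant than in the wild type in anoxic glycerol (20 adjusted over the list alone, camera adjusted p = 1.30e-07, adjusted p = 0.129 with an estimated correlation), and 16 in anoxic propionate (17 adjusted over the list alone, camera adjusted p = 8.77e-05, adjusted p = 0.346 with an estimated correlation). In glycerol the genotype difference of rng, which encodes ribonuclease G, depended on oxygen supply (log2 change 1.38 ± 0.21, adjusted p = 0.00104). Mutant against wild type, rng stood at 549 ± 22.1 against 293 ± 21.2 CPM in anoxic glycerol and 482 ± 16.1 against 331 ± 18.5 CPM in anoxic propionate, but at 222 ± 10 against 308 ± 24.5 CPM in oxic glycerol and 232 ± 15.4 against 291 ± 37 CPM in oxic propionate.

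The third pattern weighed is the level of prp transcripts in wild type oxic glycerol, where prpB had 779 ± 85.0 CPM without added propionate, against 2.09 ± 2.96 in the mutant. A shared cAMP-CRP state cannot be told apart from other sources: the maltose and galactose transport list, also under CRP, changed by a median of -0.144 (SD 0.465) between mutant and wild type there, with 7 members above and 8 below 0. Its 2 called genes, mglA (-0.92, adjusted p = 0.0159) and mglB (-1.02, adjusted p = 0.0335), were lower in the mutant, as prpB was, but by far less. Both calls ended without either library of wild type or mutant oxic glycerol (adjusted p from 0.0606 to 0.185). Propionyl-CoA from threonine degradation stays open as well: the tdc list had a median of -1.048, with adjusted p from 0.0517 (tdcD) to 0.764 (tdcA) among its 6 tested genes. A difference between the strains in propionate use stays open as the untested biological explanation.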
